A study of Mus musculus with 6 samples.

How the data were processed

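Poly(A)-selected RNA from RAW264.7 cells, a mouse macrophage line, was sequenced as 6 libraries, 3 carrying the label Blank and 3 the label ATP. Per the labels, messenger RNA was captured on oligo(dT) beads, fragmented, reverse transcribed with random hexamers and amplified by PCR. The labels do not state whether the library kit kept strand. Per the submitters' processing notes, Trimmomatic 0.36 and HISAT2 2.2.1 were used. The deposited table, whose name refers to RSEM, gives TPM (transcripts scaled to a fixed total per library) for 57180 genes at 2 decimals, with Ensembl gene identifiers, symbols, biotypes and GO and KEGG annotation. The genome build and annotation release are not given in the sources used here.

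The values are TPM as the authors deposited them, so each library sums to nearly the same total (999737 to 1000263) and holds no information on its sequencing depth. Depth is unknown, and no counting interval or detection floor is given. TPM are shares of a library: a gene or class that takes more of the total lowers the value of every other gene. A value of 0 in such a table can be a failed estimate. In 136 genes, 4 of them protein-coding, 1 library was listed at 0 while another of the same group reached at least 5 TPM, so genes listed at 0 are described as such, with each library's value.

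All 6 value columns matched a sample by its title. Groups came from the sample titles. Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(TPM + 1), ATP minus Blank, two-sided, for the 12148 genes with a mean of at least 1 TPM over the 6 libraries. Of these, 10525 were annotated as protein-coding, 934 as lncRNA and 402 as processed pseudogenes. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(TPM + 1) scale understate the change of genes with low values. Means are given with the SD of 3 libraries, and log2 fold changes with the standard error (SE) of the limma fit. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

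Before the data were examined, 45 gene lists, the alternatives and the rule for naming genes were fixed. Named genes are the 12 largest increases and 12 largest decreases among called genes with at least 5 TPM in the higher group and no overlap between groups, leaving out predicted genes, pseudogenes and genes without a symbol. To these are added up to 4 called members of each list by size of change, and Tnf, Il1b, Il6, Il10, Nos2, Ptgs2, Arg1, Mrc1, P2rx7, Entpd1, Slc25a4, Slc25a5, Hif1a, Hmox1, Ppargc1a and Mki67. Any other gene is said to have been chosen after its values were seen. The lists cover cytokines, macrophage activation, interferon, NF-kB and Toll-like receptor signalling, purinergic signalling, mitochondrial carriers, energy metabolism, stress responses, lysosome and phagocytosis, lipids, cell death, cell cycle, ribosomes, iron, osteoclast and matrix genes, and markers of 6 other cell types. Lists with at least 3 measured members (39) were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Measured members are those past the filter on mean TPM, so a member near 0 in Blank was measured only if it was higher in ATP. This can raise the share called higher. Measured were 13 of 20 listed classical activation markers, 26 of 32 cytokines and chemokines and 14 of 30 matrix genes. The lists overlap, with 56 genes in more than 1 of them. GO and KEGG terms with 10 to 500 tested genes were tested with a two-sided Fisher's exact test against tested genes carrying any term of that kind, separately for genes called higher and lower.

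Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum mean of 5 TPM, quantile normalization, median-of-ratios scaling, rescaling after leaving out mitochondrially encoded genes and the 50 genes of highest mean TPM, eBayes without trend or robust, the replicate number as a block, and leaving out each library. Count-based tests were not used because the table holds no counts. Transcript length, GC content and gene order came from GENCODE M21 (GRCm38). Since the build behind the table is unknown, no coordinates are printed.

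The limma step was tested on simulated values for 11785 genes with the spread of these libraries. It recovered 44 of 81 genes changed 1.5-fold (54.3%), 43 of 54 changed 2-fold (79.6%) and 60 of 63 changed 4-fold (95.2%), and 6 of its 153 calls were false (3.9%). Far fewer genes were changed there than the 54.5% called in the real comparison, and the simulated values were not held to a fixed total. These rates therefore need not hold for the real comparison. Camera was tested on 46 simulated lists: it called the 1 list that was moved and 0 others. The simulated genes varied independently, so false calls from list members that vary together could not appear. In the real lists the estimated correlation was 0.67 for DNA replication and 0.694 for mitosis. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

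Markers of other cell types were examined. The highest value in any library was 1.8 TPM for fibroblast markers (Lum), 0.83 for epithelial markers (Cldn7), 2.75 for T, NK and B cell markers (Cd4), 18.8 for endothelial markers (Egfl7) and 0.44 for chondrocyte and osteoblast markers (Comp). The measured endothelial marker, Egfl7, read 16.5 ± 2.37 and 12.3 ± 2.55 TPM in Blank and ATP and was not called. Of the cancer cell and melanocyte markers 2 were measured and both were called higher, Afp from 3.41 ± 0.283 to 18.0 ± 0.365 TPM and Mitf from 8.63 ± 0.864 to 11.3 ± 0.347 TPM. All genes in this paragraph were chosen after their values were seen.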

Results

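RAW264.7 cells, a macrophage-like line derived from a mouse tumour, were profiled by poly(A) RNA sequencing after 24 h of co-culture, as part of a series on a symbiosis between macrophages and bacteria that carry an ATP translocase. The 6 libraries fall into 2 groups of 3, labelled Blank and ATP. The labels state neither what ATP stands for nor which partner each group was cultured with, so the groups are called by their labels. Expression is given as TPM, mean ± SD with n = 3 per group, and log2 fold changes are ATP minus Blank on the log2(TPM + 1) scale from limma, with Benjamini-Hochberg adjusted p. The single comparison the design allows asks how the transcriptome of the ATP libraries differed from that of the Blank libraries.

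The 2 groups stood far apart. Spearman correlations across the 12148 tested genes were 0.986 to 0.987 between Blank libraries, 0.979 to 0.984 between ATP libraries and 0.903 to 0.919 between groups. The leading principal component held 75.3% of the variance and separated the groups. The next held 8.0% and set ATP 2 (-27.64) apart from ATP 1 (18.12) and ATP 3 (11.44). ATP 2 had the highest TPM of the 3 ATP libraries for Ccl3 (3855 against 2112 and 2283), Spp1 (7938 against 4025 and 4319), Lcn2, Nos2 and Hmox1, but not for Tnf (217 against 220.2 and 196). Nor was it highest for Isg15 (497 against 562 and 473) or Zbp1 (122 against 160 and 119). Of the 728 genes called at least 2-fold higher without ATP 2, 51.8% read above the mean of the other ATP libraries in it (median log2 difference 0.014). Of the 602 called at least 2-fold lower, 47.8% read below. There were 2928 genes higher in ATP than in Blank and 3694 genes lower in ATP than in Blank, together 54.5% of those tested, and 44.2% of the calls were higher. The balance between directions depended on scaling: with median-of-ratios scaling 3645 genes were higher and 3083 lower (54.2% higher), and after rescaling without mitochondrially encoded genes and the 50 most abundant genes 2414 were higher and 4907 lower (33.0% higher). That rescaling moved the median log2 fold change of tested genes from -0.07 to -0.18, a shift of -0.11, so small changes are best read relative to these medians. At least 2-fold, 750 genes were higher and 593 lower, and at least 16-fold on the log2(TPM + 1) scale, which understates changes of genes with low values, the split was 59 to 1. Groups did not overlap for 63.8% of tested genes, where chance gives 10%.

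The ATP libraries showed a strong rise of inflammatory mediators. Ptgs2, the inducible cyclooxygenase that makes prostaglandins, went from 0.633 ± 0.0252 to 656 ± 123 TPM (log2 fold change 8.63 ± 0.13 SE, adjusted p = 2.57e-07). Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, was listed at 0 in every Blank library and at 442, 1043 and 693 TPM in the ATP libraries. Il1b rose from 0.297 ± 0.244 to 188 ± 40.9 TPM (log2 fold change 7.18 ± 0.18 SE, adjusted p = 4.93e-07) and Tnf from 16.9 ± 1.95 to 211 ± 12.9 TPM. Il6 was listed at 0 in every Blank library and at 40.6, 75.9 and 54.2 TPM in the ATP libraries. Of 26 measured inflammatory cytokines and chemokines 25 were called higher and 0 lower, 25 also adjusted over the list alone, with a median log2 fold change of 3.38. Among the chemokines, which draw leukocytes, Ccl3 reached 2750 ± 961 TPM from 24.6 ± 1.55, Ccl4 781 ± 235 TPM from 2.95 ± 0.316 and Ccl5 524 ± 166 TPM from 1.89 ± 0.931. Cxcl2 read 0.07, 0 and 0 TPM in the Blank libraries and 106, 212 and 225 TPM in the ATP libraries, and Csf3, a granulocyte growth factor, 0, 0.05 and 0 against 79.0, 130 and 86.6 TPM. Il10, an anti-inflammatory cytokine, was also called higher but stayed low, at 1.36, 3.58 and 2.30 TPM. The list passed camera (adjusted p = 7.51e-17), but not with an estimated correlation (adjusted p = 0.135 with an estimated correlation).

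**Figure D1:**
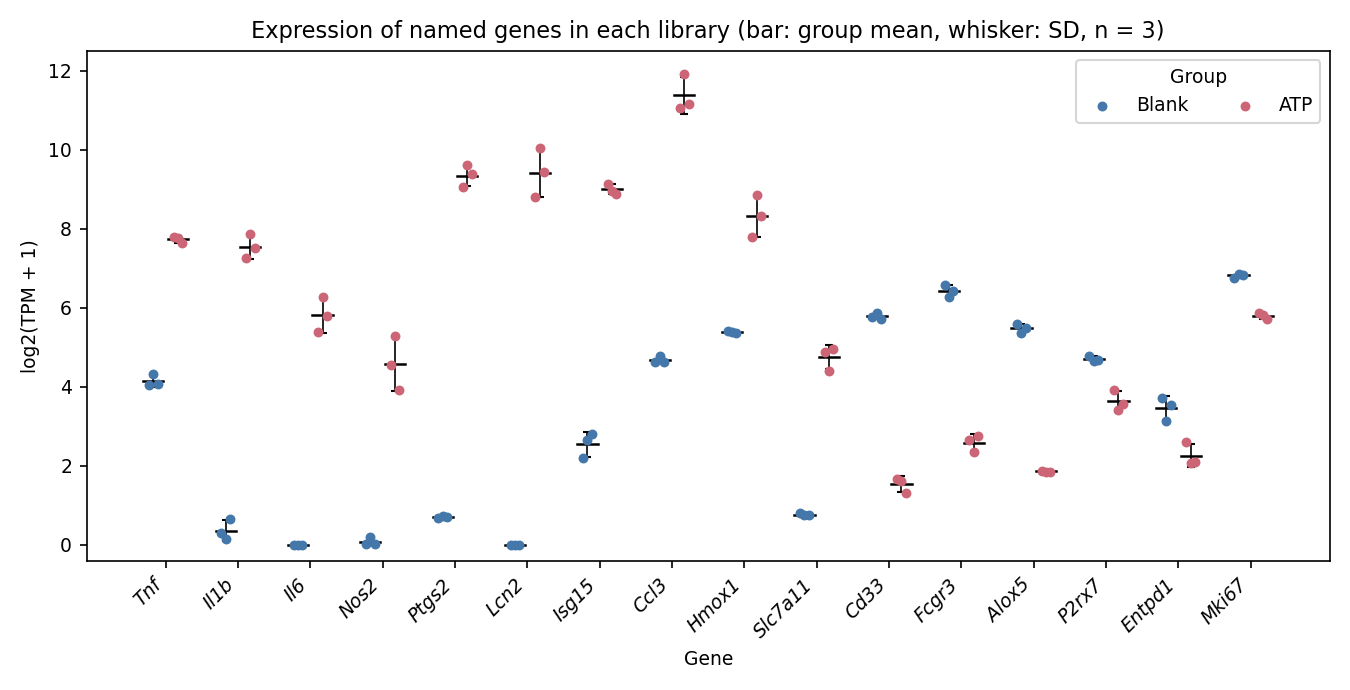
Expression of 16 named genes in each library on a log2(TPM + 1) axis. Points are single libraries, horizontal bars group means and whiskers SD (n = 3). Ptgs2 lay near 0.633 TPM in Blank and 656 TPM in ATP, Cd33 went the other way from 54.0 to 1.91 TPM, and the groups overlap for none of the genes drawn.

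Markers of classical macrophage activation rose with the cytokines, whereas those of alternative activation went both ways. Of 13 measured classical activation (M1) markers 12 were called higher and 0 lower, 12 adjusted over the list alone, with a median log2 fold change of 4.14 (camera adjusted p = 3.89e-09, and adjusted p = 0.135 with an estimated correlation). They included Acod1, which makes itaconate (0.137 ± 0.0902 to 190 ± 50.2 TPM), and the acute phase protein Saa3 (10.5 ± 1.37 to 1077 ± 230 TPM). Nos2, the inducible nitric oxide synthase, rose from 0.06 ± 0.0693 to 24.9 ± 12.2 TPM. Of 9 measured alternative activation (M2) markers 5 were called higher and 2 lower, 7 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.134, between 0.00601 and 0.22 over the alternatives, the lowest with a minimum mean of 5 TPM). The others called were Egr2, Il4ra and Tgfb1, higher, and Cd200r1, lower. Its called genes included Msr1, a scavenger receptor (1.51 ± 0.396 to 91.3 ± 33.5 TPM), Myc (0.0767 ± 0.0379 to 19.6 ± 5.06 TPM) and the lectin Clec10a, which fell from 7.74 ± 0.704 to 1.48 ± 0.0666 TPM. Mrc1 (0.913 ± 0.137 and 0.440 ± 0.128 TPM in Blank and ATP) lay below the expression filter and was not tested. The same held for Arg1, at 0, 0.37 and 0.45 TPM in Blank and 0, 0.27 and 0.41 TPM in ATP. The arginine, itaconate and nitric oxide list had 10 of 14 members higher and 1 lower (11 adjusted over the list alone, camera adjusted p = 0.000374, and adjusted p = 0.135 with an estimated correlation). Besides Acod1 and Nos2 these included Odc1, which makes putrescine from ornithine (192 ± 6.15 to 811 ± 16.8 TPM), and the mitochondrial arginase Arg2 (5.11 ± 0.685 to 20.6 ± 2.65 TPM).

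Every measured interferon-stimulated gene was higher in the ATP libraries, 41 of 41, also adjusted over the list alone, with a median log2 fold change of 2.82. Isg15, a ubiquitin-like modifier, went from 4.93 ± 1.23 to 511 ± 46.2 TPM, the nucleic acid sensor Zbp1 from 0.807 ± 0.392 to 134 ± 22.8 TPM and the antiviral enzyme Rsad2 from 1.28 ± 0.315 to 78.9 ± 15.0 TPM. The list had a camera adjusted p of 1.52e-26 and an adjusted p = 0.135 with an estimated correlation. Ifi202b, an interferon-inducible gene outside the list, rose from 1.62 ± 0.325 to 366 ± 54.4 TPM. Of 30 NF-kB pathway and feedback regulators 25 were higher and 1 lower (26 adjusted over the list alone, median log2 fold change 1.67, camera adjusted p = 4.01e-12, and adjusted p = 0.0781 with an estimated correlation). Among them were the adaptor Traf1 (2.52 ± 0.403 to 53.2 ± 0.638 TPM), Tnip3 (5.59 ± 1.87 to 98.2 ± 17.5 TPM) and the cytokine signalling inhibitor Socs3 (11.8 ± 0.390 to 169 ± 24.6 TPM). The immediate early genes had 16 of 23 members higher and 1 lower (18 adjusted over the list alone, median 1.5, camera adjusted p = 7.38e-08, and adjusted p = 0.0781 with an estimated correlation). Fosl1, an AP-1 subunit, rose from 0.257 ± 0.0709 to 26.2 ± 2.12 TPM and Ier3 from 36.2 ± 7.15 to 574 ± 29.1 TPM.

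Pattern recognition and uptake receptors changed in both directions. Of 27 Toll-like receptor and inflammasome genes 10 were higher and 10 lower (21 adjusted over the list alone, camera adjusted p = 0.421). The lipopolysaccharide co-receptor Cd14 rose from 103.2 ± 9.08 to 1092 ± 106 TPM and the inflammatory caspase Casp4 from 16 ± 2.39 to 60.7 ± 2.51 TPM. Tlr13, a sensor of bacterial ribosomal RNA, fell from 18.8 ± 3.39 to 6.05 ± 0.717 TPM and the flagellin receptor Tlr5 from 2.17 ± 0.301 to 0.147 ± 0.123 TPM. Of 23 phagocytic and scavenger receptors 12 were higher and 8 lower (20 adjusted over the list alone, camera adjusted p = 0.116, between 0.0493 after the rescaling and 0.244 over the alternatives). The C-type lectins Clec4e (4.26 ± 0.296 to 120 ± 25.6 TPM) and Clec4d (7.78 ± 1.30 to 192 ± 10.7 TPM) rose, whereas the Fc gamma receptor Fcgr3 fell from 84.8 ± 9.29 to 5.02 ± 0.872 TPM. Of 20 antigen presentation genes 17 were higher and 1 lower (18 adjusted over the list alone, median log2 fold change 1.10, camera adjusted p = 1.62e-08, and adjusted p = 0.135 with an estimated correlation). The class I genes H2-Q6 (33.7 ± 2.27 to 124 ± 8.42 TPM) and H2-Q7 (13 ± 0.796 to 39.6 ± 1.85 TPM) and the checkpoint ligand Cd274 (2.97 ± 0.318 to 17.7 ± 1.48 TPM) rose, while H2-DMa, a class II loading factor, fell from 23.6 ± 1.23 to 7.21 ± 1.04 TPM. Of 19 macrophage identity genes 8 were higher and 6 lower (14 adjusted over the list alone, camera adjusted p = 0.172), the chemokine receptor Cx3cr1 falling from 53.5 ± 8.23 to 22.3 ± 1.86 TPM.

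Among decreases the largest on the log2(TPM + 1) scale was in Cd33, a sialic acid-binding receptor, from 54.0 ± 2.69 to 1.91 ± 0.388 TPM (log2 fold change -4.25 ± 0.11 SE, adjusted p = 5.12e-07). In mean TPM Cd33 was 28.2-fold lower, while Siglech was 100.1-fold and Hmgn3 31.4-fold lower. Siglech, of the same receptor family, fell from 11 ± 0.766 to 0.110 ± 0.0361 TPM. Alox5, the 5-lipoxygenase that starts leukotriene synthesis, fell from 43.6 ± 3.72 to 2.62 ± 0.0361 TPM (log2 fold change -3.62 ± 0.08 SE, adjusted p = 4.62e-07), and Ptgs1, the constitutive cyclooxygenase, from 62.4 ± 2.77 to 9.85 ± 2.17 TPM. With Ptgs2 and the prostaglandin E synthase Ptges (0.447 ± 0.203 to 25.1 ± 7.84 TPM) moving up, the prostaglandin and eicosanoid list had 6 of 16 members higher and 8 lower (15 adjusted over the list alone). Its median was 0.01, its mean -0.01 and its camera adjusted p = 0.748. Other large decreases were in Mxd4, Cbr2, Apoc2, Rgs2, Hmgn3, St6gal1 and Gpr15lg, with log2 fold changes from -3.32 for Mxd4 to -2.79 for Gpr15lg. Another large increase was in the inhibitory receptor gene Lilrb4b (0.570 ± 0.236 to 199 ± 92.9 TPM).

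Genes for purinergic signalling and mitochondrial nucleotide exchange, the lists nearest to the subject of the series, included calls in both directions. So did all tested genes, of which 54.5% were called. Of 20 purinergic receptor and nucleotide-handling genes 7 were higher and 9 lower (17 adjusted over the list alone). The list had a median of 0.02, a mean of -0.06 and a camera adjusted p of 0.775, and its median lay between -0.41 and 0.11 over the alternatives, with -0.02 for quantile normalization, -0.08 after the rescaling and -0.12 without ATP replicate 1. P2rx7, the ATP-gated channel upstream of the inflammasome, fell from 25.1 ± 1.29 to 11.5 ± 2.31 TPM (log2 fold change -1.08 ± 0.13 SE, adjusted p = 0.000446). Entpd1, the ectonucleotidase that degrades extracellular ATP, fell from 10.2 ± 2.17 to 3.84 ± 1.04 TPM, and the uridine diphosphate receptor P2ry6 from 31.0 ± 0.945 to 10.5 ± 3.03 TPM. Adora2b, an adenosine receptor, rose from 2.81 ± 0.506 to 8.11 ± 1.15 TPM. Of 23 mitochondrial carrier genes 8 were higher and 7 lower (15 adjusted over the list alone, median 0.02, camera adjusted p = 0.472), and that median was -0.09 after the rescaling. The ADP/ATP carrier Slc25a4 fell from 129 ± 0.724 to 97.0 ± 3.02 TPM (adjusted p = 0.00046). Its paralog Slc25a5 read 684 ± 4.88 and 612 ± 41.8 TPM in Blank and ATP, with an adjusted p of 0.0472 that lay between 0.0026 and 0.307 over the alternatives, highest with median-of-ratios scaling. The pyrimidine nucleotide carrier Slc25a33 rose from 7.15 ± 0.269 to 22.7 ± 1.57 TPM.

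Central metabolism was partly shifted. Of 25 glycolysis genes 15 were higher and 7 lower (22 adjusted over the list alone, median 0.45, camera adjusted p = 0.0148, and adjusted p = 0.525 with an estimated correlation). The glucose transporter Slc2a1 rose from 32.0 ± 3.96 to 104 ± 23.2 TPM and Pfkfb3, which makes an activator of glycolysis, from 13.7 ± 1.28 to 31.7 ± 5.64 TPM. Slc2a6 fell from 38.1 ± 3.12 to 16.7 ± 0.801 TPM. Of 26 TCA cycle genes 16 were higher and 1 lower (17 adjusted over the list alone, median 0.25, camera adjusted p = 0.000302, and adjusted p = 0.331 with an estimated correlation), among them Mdh2 (228 ± 5.26 to 354 ± 9.14 TPM) and Pdha1 (30.1 ± 0.995 to 44.2 ± 0.912 TPM). Quantile normalization left 7 TCA genes higher and 3 lower and a camera adjusted p of 0.127, in a range of 1.03e-06 to 0.127 over the alternatives. The lower gene was Mdh1. Of 23 fatty acid oxidation genes 2 were higher and 11 lower (13 adjusted over the list alone, median -0.25, camera adjusted p = 0.172), with the carnitine acyltransferase Cpt1a falling from 23.2 ± 1.33 to 6.78 ± 1.16 TPM. Of 23 genes of AMPK, mTOR and energy sensing 3 were higher and 11 lower (15 adjusted over the list alone, median -0.28, camera adjusted p = 0.135), with the AMPK subunit Prkag2 falling from 30.5 ± 0.620 to 11.3 ± 0.36 TPM. Hif1a rose from 29.8 ± 1.57 to 66.9 ± 7.78 TPM, but of 20 hypoxia targets 7 were higher and 6 lower (14 adjusted over the list alone, camera adjusted p = 0.388). Vegfa and Ero1a rose, to 46.1 ± 12.7 and 179 ± 35.8 TPM, and Ankrd37 fell to 4.11 ± 2.02 TPM.

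Transcripts encoded in mitochondria took 15.4% ± 0.0900 of TPM in the Blank libraries and 12.4% ± 0.580 in the ATP libraries. Of 15 such transcripts 8 were lower and 1 higher (9 adjusted over the list alone, median -0.33, camera adjusted p = 0.0284, and adjusted p = 0.215 with an estimated correlation). Among them mt-Cytb fell from 11587 ± 133 to 6034 ± 999 TPM, whereas the ribosomal RNA mt-Rnr1 rose from 608 ± 16.9 to 1028 ± 114 TPM. The call for this list was lost with quantile normalization (adjusted p = 0.143), with median-of-ratios scaling (adjusted p = 0.0742) and without ATP replicate 1 (adjusted p = 0.0874), in a range of 0.00539 to 0.143 over the alternatives. Of 69 nuclear-encoded oxidative phosphorylation subunits 10 were higher and 24 lower (34 adjusted over the list alone, median -0.11, camera adjusted p = 0.281). This balance turned with scaling, to 17 higher and 13 lower with median-of-ratios scaling, while quantile normalization gave 4 higher and 46 lower (camera adjusted p = 2.74e-06) and the rescaling 7 higher and 41 lower (camera adjusted p = 0.035), and the range over the alternatives was 2.74e-06 to 0.798. Uqcrh fell from 1199 ± 28.1 to 792 ± 88.1 TPM and cytochrome c (Cycs) rose from 76.5 ± 3.86 to 102 ± 5.33 TPM. Of 29 genes of mitochondrial biogenesis, dynamics and mitophagy 6 were higher and 7 lower (12 adjusted over the list alone, camera adjusted p = 0.470), including the matrix protease Lonp1 (44.8 ± 2.30 to 108 ± 4.07 TPM) and the mitophagy kinase Pink1 (8.81 ± 2.48 to 4.28 ± 0.472 TPM). Ppargc1a stayed at or below 0.05 TPM in every library and was not tested.

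**Figure D2:**
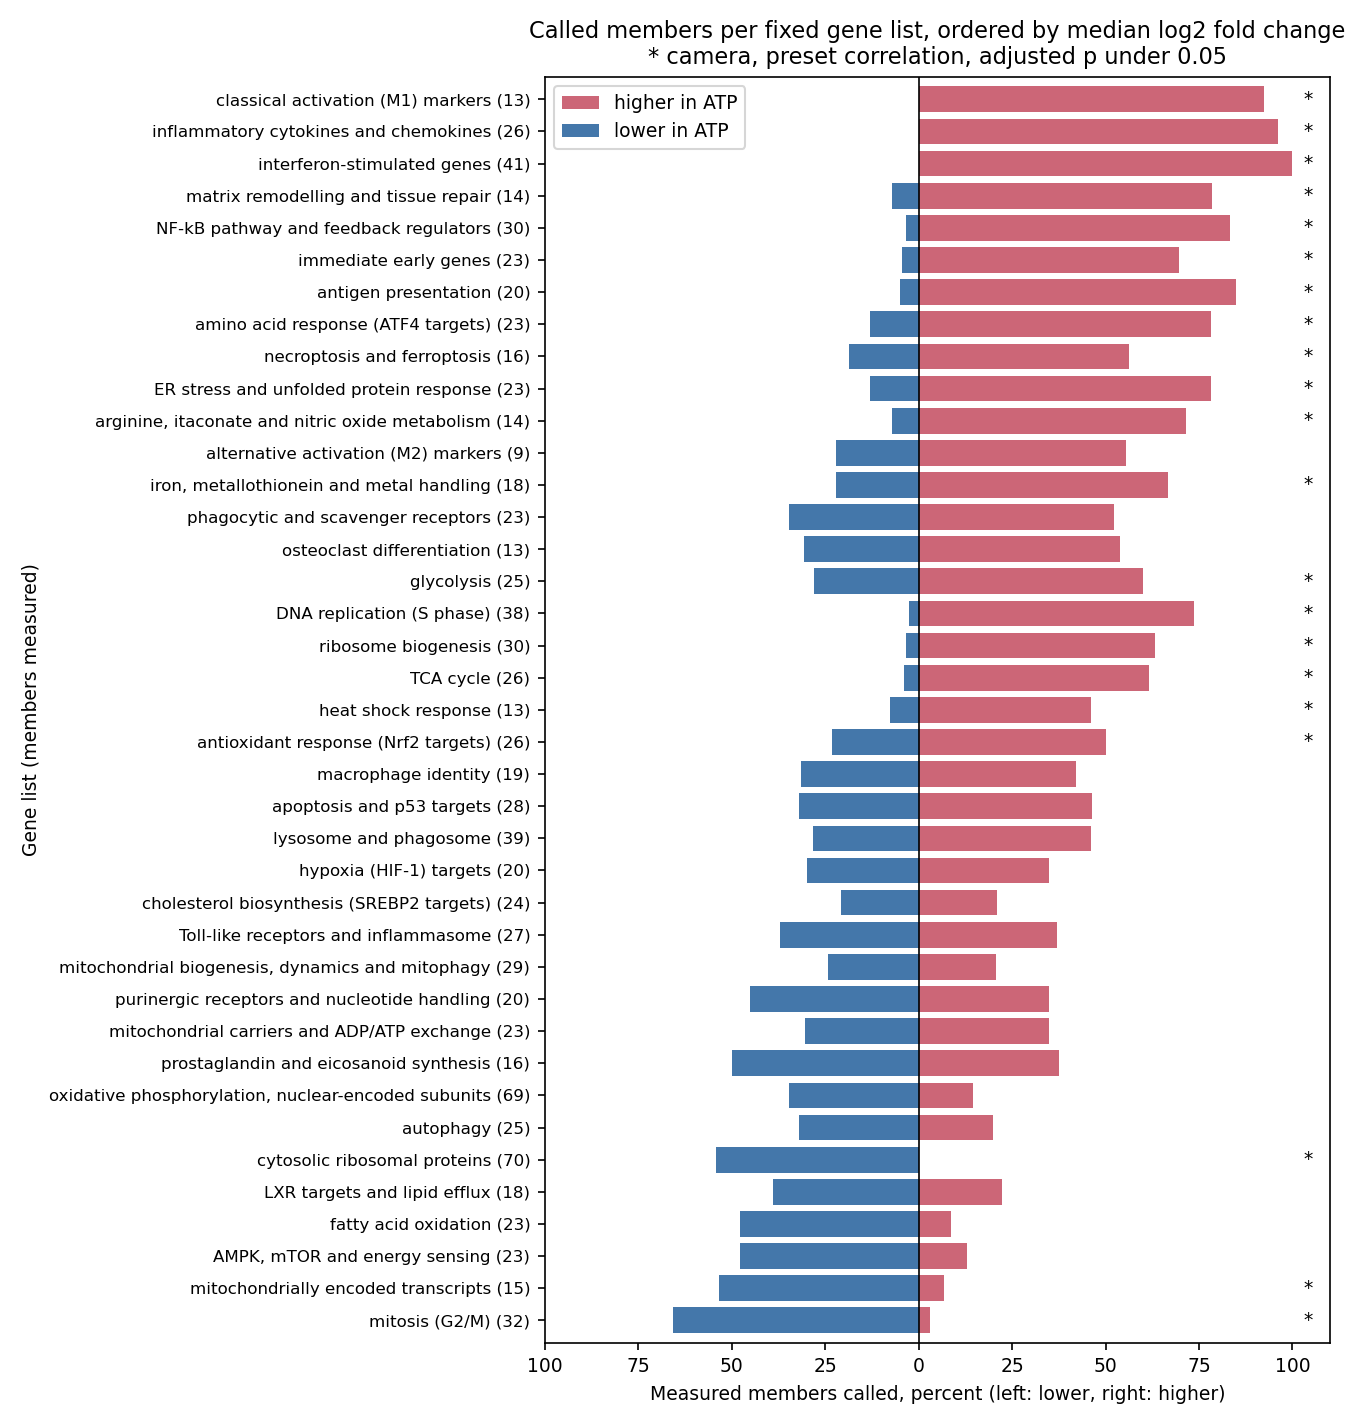
Percentage of each list's measured members called higher (right, red) or lower (left, blue) in the ATP libraries, for 39 lists ordered by median log2 fold change. Asterisks mark lists past camera with the preset correlation. Interferon-stimulated genes reach 41 of 41 higher, and mitosis genes show 21 of 32 lower.

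In each stress response list more members were called higher than lower. Of 23 genes of ER stress and the unfolded protein response 18 were higher and 3 lower (21 adjusted over the list alone, median 0.72, camera adjusted p = 2.96e-06, and adjusted p = 0.363 with an estimated correlation). The chaperone Hspa5 rose from 465 ± 38.1 to 1333 ± 364 TPM and the ER-resident Creld2 from 39.0 ± 0.380 to 144 ± 6.62 TPM. Of 23 ATF4 targets 18 were higher and 3 lower (21 adjusted over the list alone, median 0.95, camera adjusted p = 4.94e-06, and adjusted p = 0.331 with an estimated correlation), including Ddit3, which encodes CHOP (16.5 ± 2.27 to 93.6 ± 26.7 TPM), and Chac1 (1.5 ± 0.147 to 9.71 ± 2.26 TPM). Of 26 Nrf2 targets 13 were higher and 6 lower (19 adjusted over the list alone, median 0.22, camera adjusted p = 0.00848, and adjusted p = 0.457 with an estimated correlation), and quantile normalization ended the call (adjusted p = 0.22, in a range of 0.00166 to 0.22 over the alternatives). The cystine transporter Slc7a11 rose from 0.700 ± 0.0346 to 26.3 ± 5.41 TPM, and the haem oxygenase Hmox1 from 41.1 ± 0.707 to 332 ± 121 TPM (log2 fold change 2.92 ± 0.23 SE, adjusted p = 6.19e-05). Of 13 heat shock genes 6 were higher and 1 lower (8 adjusted over the list alone, median 0.23, camera adjusted p = 0.0193, and adjusted p = 0.499 with an estimated correlation), with Hsp90aa1 going from 606 ± 5.85 to 1211 ± 77.3 TPM. That call was lost with quantile normalization (adjusted p = 0.0779) and without ATP replicate 3 (adjusted p = 0.0567), in a range of 0.00139 to 0.0779 over the alternatives. The lower gene was Hsf1.

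Cell cycle genes split by phase. Of 38 DNA replication (S phase) genes 28 were higher and 1 lower (31 adjusted over the list alone, median 0.41, camera adjusted p = 1.19e-07, and adjusted p = 0.450 with an estimated correlation). Orc1, of the origin recognition complex, rose from 5.57 ± 0.702 to 13.6 ± 1.08 TPM and the polymerase clamp Pcna from 229 ± 22.4 to 410.5 ± 25.6 TPM. Of 32 mitosis (G2/M) genes 1 was higher and 21 lower (23 adjusted over the list alone, median -0.40, camera adjusted p = 0.000319, and adjusted p = 0.525 with an estimated correlation). The proliferation marker Mki67 fell from 112 ± 3.58 to 54.3 ± 2.80 TPM (log2 fold change -1.03 ± 0.06 SE, adjusted p = 1.59e-05), and Cenpf from 35.9 ± 0.973 to 15.5 ± 2.09 TPM. Of 70 cytosolic ribosomal protein genes 38 were lower and 0 higher (38 adjusted over the list alone, median -0.18, camera adjusted p = 8.47e-05, and adjusted p = 0.456 with an estimated correlation), and median-of-ratios scaling left 12 lower and 1 higher. Rps9 fell from 2847 ± 40.0 to 2143 ± 32.7 TPM. Many of these genes have processed copies in the genome that could share their reads. Of 30 ribosome biogenesis genes 19 were higher and 1 lower (21 adjusted over the list alone, median 0.28, camera adjusted p = 7.74e-05, and adjusted p = 0.448 with an estimated correlation), including Rrp9 (30.1 ± 1.85 to 62.1 ± 6.09 TPM) and Bop1 (37.7 ± 1.88 to 59.8 ± 4.35 TPM).

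**Figure D3:**
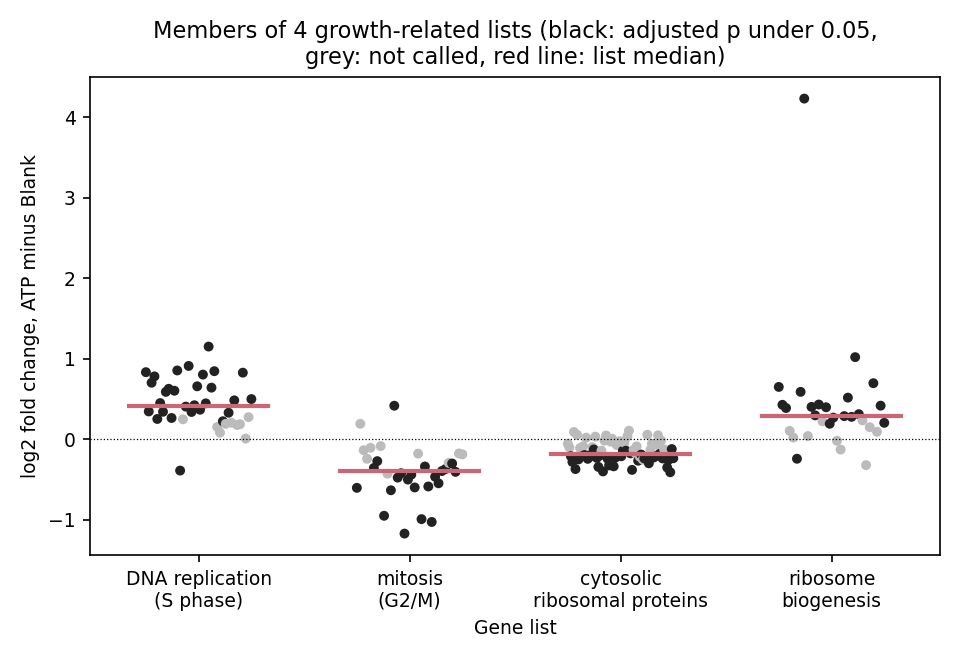
Log2 fold change (ATP minus Blank) of each measured member of the DNA replication, mitosis, cytosolic ribosomal protein and ribosome biogenesis lists. Black points are called, grey points are not, and red lines mark list medians, which were 0.41, -0.40, -0.18 and 0.28. The ribosome biogenesis point above 4 is Myc.

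Genes of matrix remodelling and tissue repair were higher in 11 of 14 cases and lower in 1 (13 adjusted over the list alone, median 2.18, camera adjusted p = 2.35e-07, and adjusted p = 0.161 with an estimated correlation). Osteopontin (Spp1) rose from 220 ± 23.5 to 5427 ± 2180 TPM and the urokinase receptor Plaur from 19.4 ± 2.93 to 167 ± 23.4 TPM. Of 18 genes of iron and metal handling 12 were higher and 4 lower (17 adjusted over the list alone, median 0.56, camera adjusted p = 0.00575, and adjusted p = 0.135 with an estimated correlation), including the phagosomal metal transporter Slc11a1 (60.5 ± 3.76 to 283 ± 14 TPM) and ceruloplasmin, Cp (1.23 ± 0.445 to 24.0 ± 12.8 TPM). Of 16 necroptosis and ferroptosis genes 9 were higher and 3 lower (12 adjusted over the list alone, median 0.72, camera adjusted p = 0.0015, and adjusted p = 0.135 with an estimated correlation). The largest changes in that list were in Ptgs2, Zbp1, Slc7a11 and Chac1, which also stand in other lists. Of 28 apoptosis and p53 targets 13 were higher and 9 lower (22 adjusted over the list alone, camera adjusted p = 0.132, between 0.0425 without a filter on low TPM and 0.277 over the alternatives). The death receptor Fas rose from 2.47 ± 0.0929 to 23.8 ± 2.10 TPM and Trp53inp1 fell from 33.8 ± 5.30 to 5.63 ± 0.283 TPM. Of 13 osteoclast differentiation genes 7 were higher and 4 lower (12 adjusted over the list alone, camera adjusted p = 0.0502, between 0.0212 and 0.0952 over the alternatives and under 0.05 in 9 of them, among them leaving out any 1 library but ATP replicate 3), with tartrate-resistant acid phosphatase, Acp5, rising from 2.35 ± 0.376 to 16.2 ± 1.97 TPM.

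Genes of the lysosome, autophagy, cholesterol synthesis and lipid efflux included calls in both directions, as did all tested genes (54.5% called). Of 39 lysosome and phagosome genes 18 were higher and 11 lower (29 adjusted over the list alone, camera adjusted p = 0.174), with Cd63 rising from 144 ± 9.73 to 350 ± 17.1 TPM and Gpnmb falling from 18.5 ± 6.19 to 3.67 ± 1.05 TPM. Of 25 autophagy genes 5 were higher and 8 lower (13 adjusted over the list alone, camera adjusted p = 0.496), with the cargo receptor Sqstm1 rising from 140 ± 5.66 to 565 ± 125 TPM and the kinase Ulk1 falling from 8.26 ± 1.47 to 4.14 ± 0.610 TPM. Of 24 cholesterol biosynthesis genes 5 were higher and 5 lower (9 adjusted over the list alone, camera adjusted p = 0.721), Hsd17b7 rising from 18.3 ± 2.24 to 35.1 ± 2.25 TPM. Of 18 LXR targets and lipid efflux genes 4 were higher and 7 lower (11 adjusted over the list alone, camera adjusted p = 0.276). Apolipoprotein E (Apoe) fell from 21.2 ± 1.10 to 2.85 ± 0.585 TPM and the fatty acid transporter Cd36 rose from 3.92 ± 0.438 to 50.7 ± 18.3 TPM.

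Over the 39 lists camera called 21, 18 of them higher and 3 lower, and 0 with an estimated correlation. With 3 libraries per group, fry, which asks only whether a list's genes move and does not compare them with other genes, called 34 by direction and 39 in either direction. Exceptions within the lists that stand outside the naming rule were chosen after their values were seen. These are Tnfsf9 among cytokines and Cd86 among classical activation markers, both not called. They also include Il4ra, Tgfb1 and Cd200r1 among alternative activation markers. Called lower were Cyld among NF-kB regulators, Btg2 among immediate early genes, Gins3 among DNA replication genes, Gnl3 among ribosome biogenesis genes, Igf1 among matrix genes, Pts among arginine and nitric oxide genes, Mdh1 and Hsf1. The same held for Xbp1, Atf6 and Eif2ak3 of the ER stress list, Sesn2 and Stc2 beside Ddit4 of the ATF4 list, Ripk1, Fadd and Ncoa4 of the necroptosis and ferroptosis list, and Mt1, Mt2, Slc40a1 and Ncoa4 of the iron list. Ocstamp, Traf6, Clcn7 and Ostm1 of the osteoclast list were lower too. Called higher were Cdk1 among mitosis genes, Prkaa1 and Tsc2 beside Arrdc4 in energy sensing, Acadvl beside Hilpda in fatty acid oxidation, and Atg13, Gabarap, Gabarapl1 and Wipi2 beside Sqstm1 in autophagy. Lpl and Plin2 beside Abca1 and Cd36 were the higher LXR targets. In cholesterol biosynthesis the higher genes included Fdft1, Msmo1 and Srebf2 beside Hsd17b7, and the lower ones Mvd and Stard4 beside Dhcr7 and Insig1.

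Members of families with near-identical sequence, such as Lilrb4b, Bcl2a1b, H2-Q6, H2-Q7 and Ifi202b, could share reads with their relatives, so their single values are uncertain.

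Among the deposited annotation terms, 36 KEGG pathways and 89 GO terms were enriched among genes called higher, against 1 and 7 among genes called lower. Fisher's exact test treats genes as independent, so its p-values may be too small for genes that move together. Terms can also share genes, so these are not counts of separate themes. The KEGG proteasome pathway had 39 of 43 tested genes higher where 12.6 were expected (Fisher's exact test, adjusted p = 1.97e-14), protein processing in the endoplasmic reticulum 78 of 146 (42.6 expected, adjusted p = 1.47e-07) and antigen processing and presentation 31 of 48 (14 expected, adjusted p = 2.31e-05). The GO term for DNA replication initiation had 12 of 16 genes higher (3.9 expected, adjusted p = 0.00286). Among genes called lower, the KEGG calcium signaling pathway held 42 of 85 (26.3 expected, adjusted p = 0.0061). The GO terms for DNA-templated regulation of transcription, with 189 of 441 (133.8 expected, adjusted p = 4.28e-06), and for fatty acid beta-oxidation, with 19 of 32 (9.7 expected, adjusted p = 0.0324), were also enriched there.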

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

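All alternatives were planned before the data were examined. The counts of genes higher in ATP than in Blank and of genes lower in ATP than in Blank stayed within 1.5 times the reported ones under each alternative, apart from the following. With a pseudocount of 5, 477 genes were at least 2-fold higher and 227 at least 2-fold lower, since a larger pseudocount shrinks the fold change of genes with low values. Rescaling without mitochondrially encoded genes and the 50 most abundant genes gave 899 genes at least 2-fold lower. The top 50 genes took 35.5% ± 0.23 of TPM in Blank and 30.6% ± 1.11 in ATP. Rescaling the rest therefore raised Blank values more, and the median log2 fold change moved by -0.106. More genes also passed the filter (12826 against 12148), and how much each of these added was not tested. Of the list tests, camera called 21, camera with an estimated correlation 0, fry by direction 34 and fry in either direction 39. Fry tests another question than camera. Calls also ended for lists whose estimated correlation lay below the preset 0.01. These include immediate early genes (-0.007), iron and metal handling (-0.016) and arginine, itaconate and nitric oxide genes (-0.048). A higher correlation among members thus cannot be why these lists lost their calls, and what else ended them was not tested. Leaving out 1 library at a time gave 2455 to 3124 genes higher, 2925 to 3693 lower, 728 to 765 at least 2-fold higher and 544 to 659 at least 2-fold lower. Of the counts of called list members under the alternatives, 66 moved by more than 1.5 times and 1180 did not. In the annotation term enrichment 133 terms were enriched as reported, 191 against all tested genes and 185 with calls of at least 2-fold. Of the 6622 reported calls 5878 were also called with quantile normalization, 1 of them in the opposite direction, 6011 with median-of-ratios scaling and 6006 after the rescaling, 0 of them reversed in either.

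The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.081, -0.081 and 0.007, against a highest value of 0.091 between libraries of different numbers. With the replicate number as a block, there were 2794 genes higher in ATP than in Blank and 3548 genes lower in ATP than in Blank, with 752 genes at least 2-fold higher in ATP than in Blank and 599 genes at least 2-fold lower in ATP than in Blank. Of 161 named genes tested, all were called, which the naming rule largely fixed since it mostly takes called genes. Under the alternatives 2 lost their call in 17 cases with the direction kept: Hspa1b (adjusted p = 0.0486 as reported) and Slc25a5 (0.0472), the latter reaching 0.307 with median-of-ratios scaling. Depth is unknown from TPM, so low values carry an error that cannot be stated. The alternative with DESeq2 was not run because the table holds no counts.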

Other observations

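The gene groups in this paragraph were chosen after their values were seen. Proteasome genes rose together: of 47 measured genes for numbered proteasome subunits, activators and assembly chaperones 42 were higher and 1, Psmg4, lower (median log2 fold change 0.58), and quantile normalization still gave 35 higher and 1 lower. Psme2b, which resembles Psme2 and was not counted in this group, fell from 15.4 ± 2.86 to 4.24 ± 1.98 TPM. Psme2, a subunit of the interferon-inducible activator, rose from 194 ± 1.52 to 493 ± 52.6 TPM and the catalytic subunit Psmb6 from 195 ± 9.03 to 408 ± 19.3 TPM. Of 18 cytosolic aminoacyl-tRNA synthetases 16 were higher and 1 lower (median 0.74, 14 higher with quantile normalization). Cars rose from 35.9 ± 3.05 to 102 ± 7.67 TPM, Qars fell from 198 ± 21.4 to 161 ± 12.3 TPM, and Vars read 76.7 ± 0.709 and 76.5 ± 7.58 TPM. Of 17 mitochondrial synthetases 2 were higher and 4 lower. Of 273 genes with Zfp names 123 were lower and 13 higher (median -0.31), and the excess of lower calls held with quantile normalization (106 to 17) and median-of-ratios scaling (109 to 16). Zfp36, which destabilizes cytokine messenger RNA, rose from 17.1 ± 1.27 to 109 ± 20.5 TPM.

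A set of 9 protein-coding genes had at most 0.1 TPM in every Blank library and at least 10 TPM in every ATP library, and 0 genes did the reverse. Besides Il6, Lcn2, Csf3, Cxcl2 and Mmp9 these were Gstt4, Urah, Rgs16 and Cstdc4, chosen after their values were seen. Gstt4 was listed at 0 in all Blank libraries and at 32.9, 33.3 and 26.1 TPM in the ATP libraries. Urah, of the uric acid degradation pathway, was likewise listed at 0 and then at 34.6, 35.5 and 29.7 TPM. Gstt1, a glutathione transferase that lies next to Gstt4, rose from 1.54 ± 0.198 to 223 ± 32.4 TPM, and Ddt, close by, from 46.5 ± 2.62 to 465 ± 49.6 TPM. The 4 measured Gstt members were called higher in every scaling tried. They are similar in sequence, so their single values are uncertain.

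In the paragraphs below, the tests of scaling were chosen after the results were seen, as was the comparison of neighbours restricted to named, non-overlapping genes. For neighbours among the lower genes, and for genes of mean log2 TPM of at least 10, no prediction was written beforehand. The other tests were set beforehand. DNA replication genes were higher and mitosis genes lower in ATP. A single scaling factor between the groups would move both lists alike and cannot open a gap between their medians. That gap was at least 0.812 under every scaling tried. Median-of-ratios scaling and the rescaling apply such factors, so they could hardly change it and add no support. Quantile normalization could, and gave medians of 0.326 for DNA replication and -0.496 for mitosis. Transcript length, GC content and expression level were set against these shifts by drawing 10000 matched random lists: 0% had a median as extreme, with DNA replication at 0.41 (matched lists -0.13 to 0.20) and mitosis at -0.40 (-0.11 to 0.23). Genes of the random lists were drawn independently, while the estimated correlations within the DNA replication and mitosis lists were 0.67 and 0.694. The ranges may therefore be too narrow for such lists. A candidate explanation is a shift in the distribution of cells over the cell cycle, which was not tested.

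Cytosolic ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes had medians below that of all tested genes. With quantile normalization the differences were -0.079 and -0.258. The oxidative phosphorylation list did not pass camera as reported (adjusted p = 0.281, between 2.74e-06 and 0.798 over the alternatives). Relative to the median of all tested genes the value nearest 0 over the scalings was -0.072 for ribosomal proteins and -0.026 for oxidative phosphorylation, so whether either list fell in itself cannot be told apart from one scaling factor between the groups. Against genes matched on transcript length, GC content and expression level, the median of oxidative phosphorylation genes differed by -0.267, and 0% of matched lists had a lower median. The list median was -0.107, that of the matched lists 0.16 and that of all tested genes -0.072. The matched genes thus lay further from all tested genes, on the higher side, than the list did on the lower side. One factor moves the list and its matched genes alike, so it could not open this gap, and the comparison is no test of it. Scaling that moves genes unequally was not set against matched genes. With quantile normalization the list lay further below all tested genes, at -0.258 against -0.035 as reported. The 0% argues against length, GC content or expression level as the cause of the gap in the values as reported. The direction of the list in absolute terms stays open. For ribosomal proteins the difference was -0.281 and the share 0%, with a list median of -0.178 and a matched median of 0.103. Matching was incomplete there (mean log2 TPM 10.45 against 9.31 in matched genes), so transcript length, GC content and expression level stay open for that gap. One factor, which moves both alike, would not open it. Among genes of mean log2 TPM of at least 10, 41 genes outside the lists had a median of -0.05 and 53 ribosomal protein genes one of -0.18. Genes of the matched lists were drawn independently here too. The estimated correlations were 0.324 for oxidative phosphorylation and 0.282 for ribosomal proteins, so the matched ranges may be too narrow.

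Neighbours were taken as consecutive genes in the order of tested protein-coding genes along a chromosome. No limit was set on their distance, and other genes can lie between them. Genes at least 2-fold higher in ATP were neighbours in this sense more often than random placement along the chromosomes gives: 113 neighbouring pairs among 616 placed genes, against 25 to 48 when shuffled (ranges hold 95% of 10000 shufflings). Genes at least 2-fold lower also did so, with 52 pairs (13 to 30 when shuffled), 42 of them with different name stems (12 to 29 when shuffled); their strands were not compared. Reads shared between paralogs were weighed by name stems only, which compare symbols and not sequences. Relatives with other names, as Gm43302 beside Gbp9 may be, count as different, so shared reads cannot be excluded. Among the higher genes, 57 pairs had different name stems (24 to 46 when shuffled). Of these 70.2% lay on the same strand (33.3 to 59.6 in random draws of as many pairs from all neighbouring pairs with different stems). Transcription running on into the next gene on the same strand would give such an excess, but only between close genes, and distance was not weighed. Strands were compared for the higher genes only. Among named, non-overlapping genes with different stems there were 47 pairs (21 to 41 when shuffled), also 70.2% on the same strand. Tandem relatives with other names and shared regulation may give the same picture and stay open. Osm with Lif, chosen after their values were seen, is 1 of the pairs on the same strand.

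The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2928 genes higher in ATP than in Blank, 3694 lower, 750 at least 2-fold higher and 593 at least 2-fold lower, and 1 of the 10 splits gave as many for each. The highest of the other splits gave 1 gene, counted in either direction.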
